A study of Mus musculus with 2 samples.

How the data were processed

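Total RNA was extracted from the esophagus of mouse embryos at E18.5, and biotin-labelled cRNA prepared from 6 µg of RNA was hybridized to Affymetrix expression arrays, per the labels' protocols. The series holds 2 arrays, 1 from wild-type BALB/c tissue and 1 from tissue labelled as lacking both Myf5 and Myod1. The strain is named here for the wild-type array only, so a difference in strain could not be told apart from genotype. How many embryos each RNA sample came from is not given in the sources used here. The deposited values are signal intensities on a linear scale, 1 per probe set, made by the authors with MAS5 per the submitters' processing notes. MAS5 is Affymetrix's summary method, which combines the probes of a probe set into 1 signal and scales each array to a common mean. Its version and settings are not given in the sources used here. The deposited intensities had a mean of 1500 on each array after trimming 2% of probe sets from each end, so the 2 arrays share 1 scaling target. The table holds no detection calls.

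The table has 45101 probe sets, of which 64 are array controls and were left out of all gene counts. Gene names came from GEO's platform annotation, which can be old, with symbols checked by Entrez ID against the RefSeq table of the GRCm38.p6 mouse assembly, which held the ID of 34754 probe sets. Of the 45037 other probe sets, 34945 have 1 gene symbol, 932 have several and 9160 are unnamed here. Probe sets with several symbols or none were kept out of the gene counts. The named ones cover 18193 genes. A gene with several probe sets took the one with the highest mean signal over both arrays.

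The values were used as scaled by the authors. A low-signal limit, equal on both arrays, was set at the median of all non-control probe sets of both arrays together, a signal of 489. Signals below it were raised to it before log2 ratios of the null-labelled over the wild-type array were taken. A gene below the limit on both arrays (4878 genes) was treated as not measured, which left 13315 genes. A gene below it on 1 array (2969 genes) has only a bound, written "at least N-fold". For single probe sets it is given as a bound on the log2 scale. The limit stands in for detection calls and is not a background measurement.

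Each genotype has 1 array, so no statistical test between genotypes was possible and no p-value is given. Genes were counted by size, at least 2-fold apart in either direction. For each of 41 gene lists, the median log2 ratio of the measured members is given with its percentile among 10000 random lists of the same size, drawn from measured genes in 20 bins of mean signal. This percentile describes these 2 arrays only. The error that can be had is the spread of log2 ratios between probe sets of 1 gene, an SD of 0.56 pooled over 14307 probe sets of 5455 genes. It leaves out all variation between animals. The number of arrays limits the precision.

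The lists, the limit, the 2-fold rule and the rule for naming genes were fixed before the data were examined. The text names Myf5 and Myod1, then in each list up to 4 measured members with the largest ratio (or the 3 brightest where fewer than 2 members were 2-fold apart, or all members of a list with under 4 measured), and outside the lists the 10 largest ratios in each direction, leaving out predicted loci. Some were left out for length. Genes named outside this rule are marked as chosen after their values were seen.

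Alternatives were centring on the median ratio, quantile normalization, loess on signal (span 0.3), a limit at the 25th or 75th percentile, no limit with a pseudocount of 16, the median of a gene's probe sets, leaving out probe sets with IDs ending in _x_at or _s_at, a 4-fold threshold, and random lists not matched on signal. On simulated arrays with a noise SD of 0.4 (log2), the 2-fold rule called 88% of genes set 1.5 higher and 94% of those set 1.5 lower on the log2 scale. It called 0.943% of unchanged genes. That noise is below the spread between probe sets measured here. With a noise SD of 0.56, equal to that spread, the rule called 6.48% of unchanged genes, both directions counted together. It called 88% of those set 1.5 higher and 84% of those set 1.5 lower. The lists were simulated with the smaller noise only. Of 100 simulated lists of 20 genes shifted by 0.5, 99% lay above the 97.5th percentile, against 3% of unshifted lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 was used.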

Results

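Gene expression was compared between the esophagus of wild-type mouse embryos and that of embryos labelled Myf5 and Myod1 double null, at E18.5, shortly before birth. Myf5 and Myod1 encode the transcription factors that commit cells to skeletal muscle. The series title places the comparison within the replacement of smooth by striated muscle in the developing mouse esophagus. There was 1 array per genotype, with no replicate of either, so each difference compares 2 RNA samples and carries no test. The 2 arrays correlated across the 13315 measured genes with r = 0.92 on the log2 scale; genes are not independent replicates. At least 489 in signal was reached by 44.6% of probe sets on the wild-type array and 55.4% on the null-labelled array. The control ratio of 3' to 5' signal, a sign of RNA and cRNA integrity, was 12.6 and 14.2 for beta-actin and 10.5 and 6.96 for Gapdh, on the wild-type and null-labelled arrays. Both controls were thus several-fold weaker at the 5' end on both arrays. What this does to the gene ratios was not tested. In all 9 pairs of 3' and 5' probe sets of the poly-A controls, bacterial transcripts added to the RNA, the 3' log2 ratio of the null-labelled over the wild-type array was the higher, by a median of 0.83 (0.54 to 1.20), against -0.029 for 8 pairs of the hybridization controls.

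The targeted genes were examined first. Myf5 had 1 probe set, with a signal of 4072 on the wild-type array and 496 on the null-labelled array, 8.22-fold lower and next to the low-signal limit. Myod1 did not differ in this way. Its brighter probe set read 2001 and 1698, 1.18-fold lower, which is within the spread between probe sets of 1 gene. Its second probe set lay below the limit on both arrays, at 321 and 292. Where these probe sets lie relative to the deleted parts of either gene is not given in the sources used here, so the Myod1 signal checks neither the label nor the loss of the protein. The second array is therefore called the null-labelled array.

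Across all measured genes, 714 genes read at least 2-fold lower and 800 at least 2-fold higher on the null-labelled array, which is 5.36% and 6.01% of the measured genes. On simulated arrays whose noise equalled the spread between probe sets of 1 gene, 6.48% of unchanged genes passed the same threshold, both directions counted together. This share is not a rate for either direction alone. The spread was taken after low signals were raised to the limit and was larger without it, so the simulated noise may be too small. The lower group held the large differences. In it, 142 genes were at least 4-fold and 25 at least 16-fold lower, against 21 and 0 higher, and 19 of those 25 belonged to the striated muscle lists. With low signals raised to the limit, the largest ratio was 161-fold lower (Myh3) and the largest in the other direction 8.57-fold higher (Ptprc). This caps genes below the limit on 1 array, 2256 on the wild-type and 713 on the null-labelled array. The counts at 4-fold and 16-fold and this ranking hold for capped ratios only. Tnnc2 (46247 and 57.9) counted as at least 94.5-fold lower and Eif2s3y (10.6 and 2402) as at least 4.91-fold higher. With loess on signal the 2-fold counts were 938 lower and 449 higher, and with quantile normalization 804 and 546. The limit moved them further and turned their balance. They were 1232 lower and 2742 higher with the limit at the 25th percentile, 383 and 148 at the 75th, and 1704 and 3548 with no limit. The median log2 ratio of all measured genes was 0.086, and it moved to -0.021 with loess. Of the 2-fold genes with several measured probe sets, a second probe set was also 2-fold apart for 80 of 295 lower genes and 46 of 274 higher genes. All measured probe sets had the same sign for 151 of these 295 lower genes and 190 of these 274 higher genes.

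**Figure D1:**
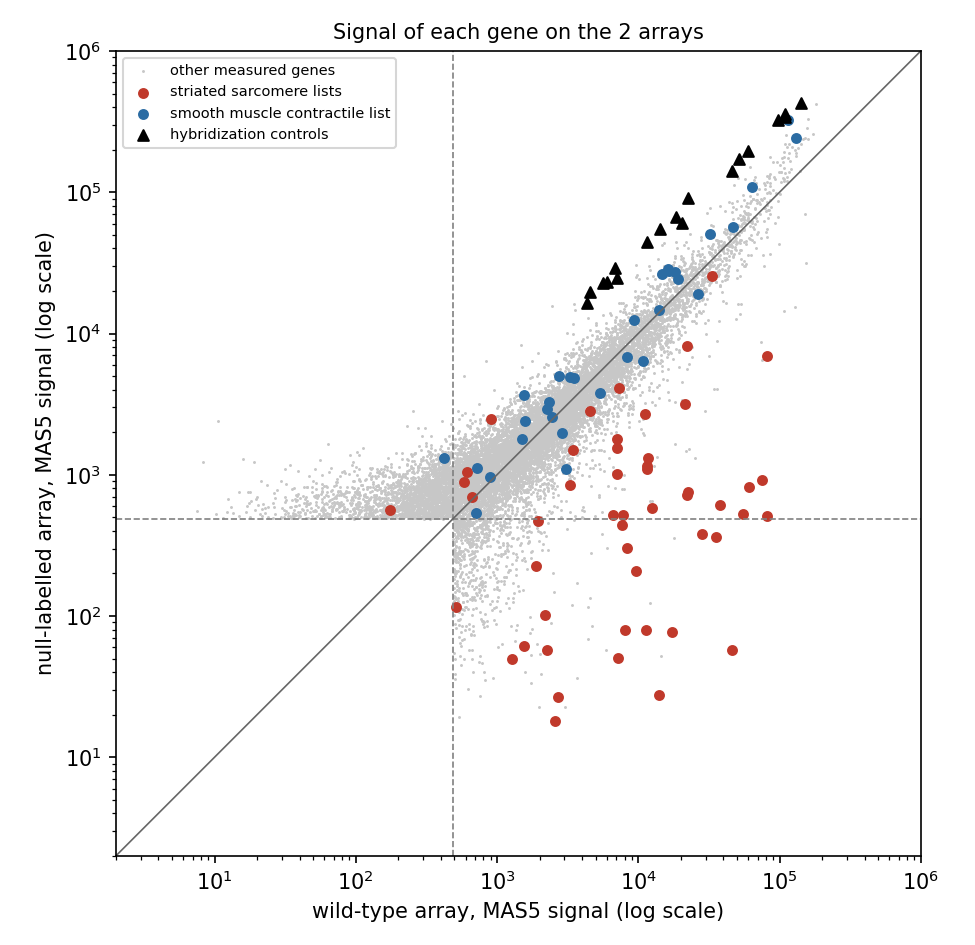
MAS5 signal of each measured gene on the wild-type array (x axis) and the null-labelled array (y axis), both on log scales, with 1 array each, so no error bars. Dashed lines mark the low-signal limit of 489 and the solid line marks equal signals. Signals are plotted as deposited, without raising them to the limit. Genes of the 4 striated sarcomere lists (red) spread far below the line. Myh3 lies 161-fold below it (log2 ratio -7.33) and Tnnc2, under the limit on the null-labelled array, lies further below (raw log2 ratio -9.64). The smooth muscle contractile list (blue) lies around and above the line, and the 18 hybridization control probe sets (black triangles) lie above it at a median of 3.57-fold.

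Striated muscle contractile genes were the most strongly lower group. Myh3, the embryonic myosin heavy chain, read 81678 on the wild-type and 507 on the null-labelled array, 161-fold lower. Myh8, the neonatal (perinatal) heavy chain, was at least 72.6-fold lower. Myl4, an embryonic and atrial light chain, was 4.16-fold lower at its brighter probe set, while its second went the other way (log2 ratio 0.48). These were the 3 measured genes of that list, with a median log2 ratio of -6.18. Of 12 measured fast fiber genes, 10 were at least 2-fold lower and 0 higher (median -3.32). Tnnc2, the fast troponin C, was at least 94.5-fold lower. The light chains Mylpf and Myl1 were 61.8-fold and at least 57.6-fold lower. Of 11 slow fiber genes, 9 were lower and 0 higher (median -3.39), among them the slow troponins Tnnt1 (31.0-fold) and Tnnc1 (29.7-fold) and Tnni1 (at least 23.0-fold). Of 24 sarcomere genes shared by striated fibers, 19 were lower and 1 higher (median -2.20). The giant elastic protein gene Ttn was 105-fold lower, the M-band gene Myom2 81.4-fold, skeletal alpha-actin Acta1 74.4-fold and alpha-actinin Actn2 at least 35.2-fold. The 1 higher gene was Smyd1 (2.76-fold), named here after its value was seen. Each of these 4 medians lay below all 10000 random lists, in the main setting and in all 8 alternatives that can move it.

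Genes that couple excitation to contraction and that regulate muscle formation were lower too. Of 14 coupling genes, 7 were at least 2-fold lower and 0 higher (median -1.28, below all random lists). Srl, which encodes the sarcoplasmic reticulum protein sarcalumenin, was 19.1-fold lower, the calcium pump regulator Sln at least 9.06-fold and the calcium release channel Ryr1 at least 7.49-fold. Of 27 myogenic regulators and progenitor genes, 12 were lower and 1 higher (median -0.84, below all random lists). Myog, the myogenic factor of differentiating myoblasts, was at least 16-fold lower, from a signal of 7839 to 456, Vgll2 at least 12.2-fold, the myoblast fusion gene Mymx at least 12.0-fold and Megf10 9.91-fold. The 1 higher gene was Pax3, a progenitor factor, with a bound of 1.32 on the log2 scale. Pax7, a marker of muscle progenitors and satellite cells, was at least 4.11-fold lower. Pax3 and Pax7 were chosen after their values were seen.

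The lists of synaptic, metabolic and membrane genes of muscle also had medians below 0. In the neuromuscular junction list, 3 of 9 measured genes were lower and 0 higher (median -0.67, 0.17th percentile). For 6 of the 9 the ratio is a bound, and the median was -1.12 with the limit at the 25th percentile. With the limit at the 75th percentile only 3 genes were measured, 0 of them 2-fold lower (median -0.46, 7.43rd percentile). The lower genes were the acetylcholine receptor subunits Chrna1 (at least 3.92-fold), Chrnb1 (at least 3.44-fold) and the fetal subunit Chrng (at least 2-fold). In the muscle energy metabolism list, 6 of 16 were lower and 0 higher (median -0.49, 0.08th percentile), with the muscle phosphoglycerate mutase Pgam2 at least 6.93-fold lower, Cox6a2 4.40-fold and Eno3 4.23-fold. Creatine kinase Ckm was 4.98-fold lower at its brighter probe set, and its second read higher, with a bound of 0.25 on the log2 scale. In the dystrophin complex list 1 of 10 was lower and 0 higher (median -0.22, 3.94th percentile, and 7.41st among random lists not matched on signal). Its brightest members Dag1, Sspn and Sgcb were 1.30-fold, 1.48-fold and 1.58-fold lower. With the limit at the 25th percentile 2 of 11 were lower (median -0.66, 0.14th percentile).

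Smooth muscle contractile genes read slightly higher as a group. Of 31 measured genes, 24 had a ratio above 0, 3 were at least 2-fold higher and 1 was 2-fold lower. The median log2 ratio was 0.45, against 0.00 ± 0.11 (SD) for the matched random lists, and it lay above all 10000. Mylk, the myosin light chain kinase, read 115515 and 326483, 2.83-fold higher, at its brightest probe set, and its other probe sets had log2 ratios of 1.86 and 0.084. Lmod1, the smooth muscle leiomodin, was at least 2.67-fold higher and the potassium channel Kcnma1 2.36-fold. Acta2, smooth muscle alpha-actin, read 131127 and 242976, and Myh11, the smooth muscle heavy chain, had a log2 ratio of 0.76; both were named after their values were seen. Des, which striated muscle also expresses, was 2.80-fold lower at its brighter probe set and higher at its second (a bound of 0.83 on the log2 scale). Mylk and Acta2 lie among the 47 genes with a wild-type signal above 98922, the brightest on that array, whose median log2 ratio was 0.58, so the size of their ratio is uncertain. With the median of each gene's probe sets, 2 genes of the list were at least 2-fold higher and 0 lower (median 0.41).

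Of 17 regulators and receptors of smooth muscle, 3 were at least 2-fold higher and 1 was lower (median 0.43, 98.7th percentile). Hhip, a Hedgehog-binding protein, was 4.25-fold higher at its brightest probe set. Its other measured probe sets had a log2 ratio of 1.04 and a bound of 1.12. Myocd, the smooth and cardiac muscle coactivator myocardin, was 2.44-fold and the endothelin receptor Ednrb 2.02-fold higher. The growth factor receptor Pdgfrb was 2.71-fold lower. The median of this list was 0.19 with a low-signal limit at the 75th percentile and 0.22 with the median of each gene's probe sets, at the 92.9th and 80.4th percentiles.

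**Figure D2:**
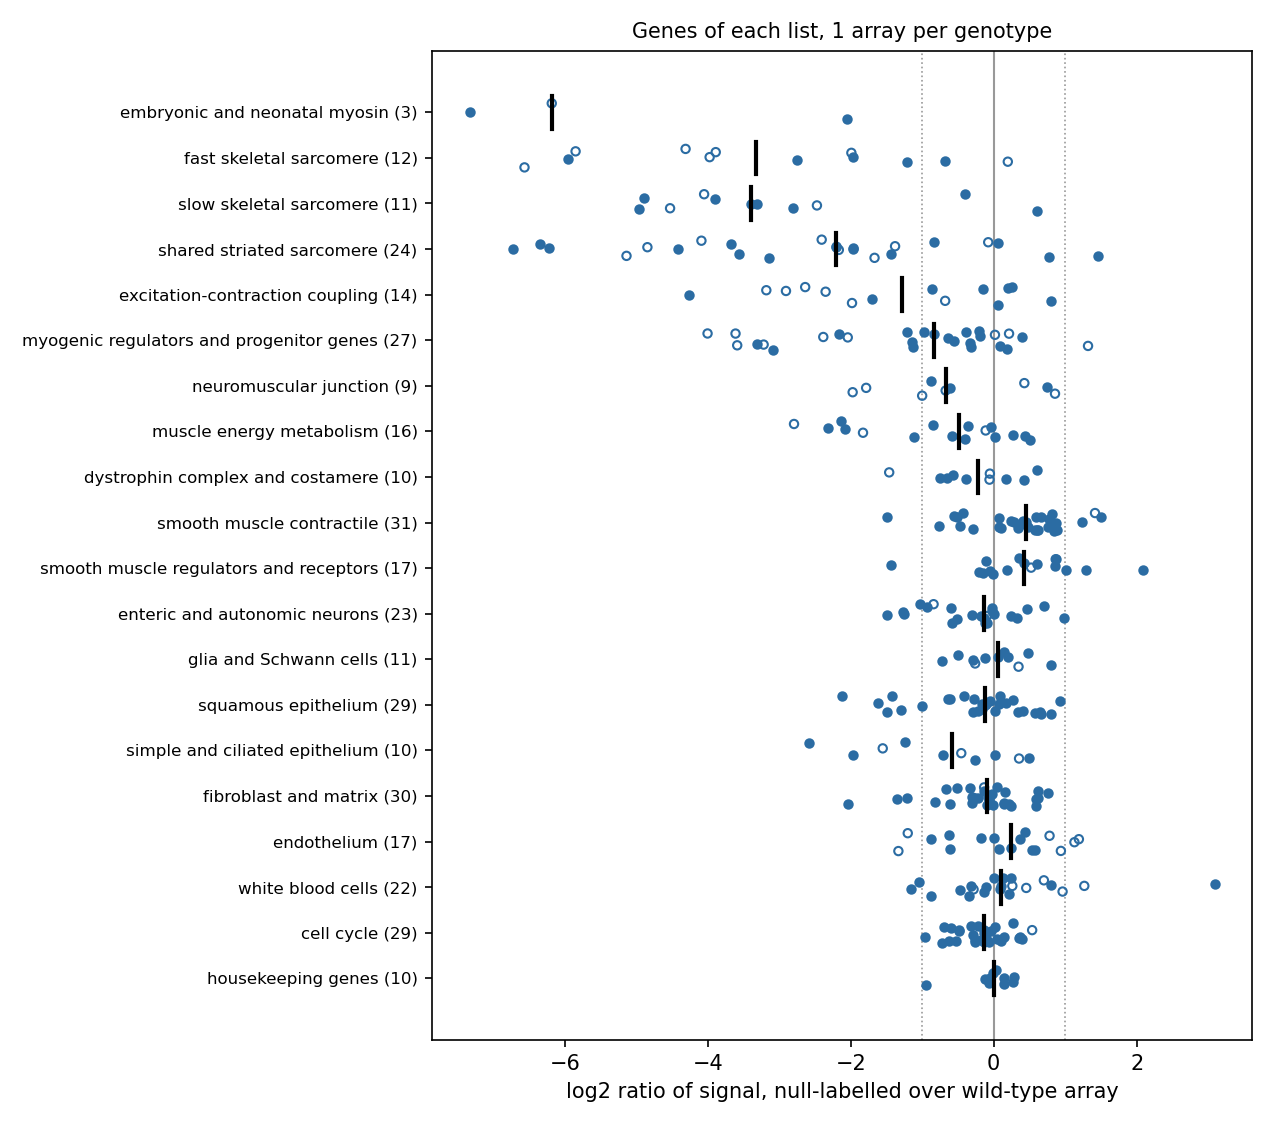
Log2 ratio of signal, null-labelled over wild-type array (x axis), for the measured genes of 20 lists (rows, number measured in parentheses), 1 array per genotype. Each point is a gene, open points are genes below the low-signal limit on 1 array (bounds), black bars are list medians and dotted lines mark 2-fold. The 4 striated sarcomere lists have medians from -6.18 to -2.20, and the smooth muscle contractile list has a median of 0.45.

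Of 23 measured enteric and autonomic neuron genes, 17 had a ratio below 0, 4 were at least 2-fold lower and 0 higher. The median was -0.14, at the 7.70th percentile, and over the alternatives it lay between the 2.08th percentile, with the limit at the 25th percentile, and the 23.4th. The 4 lower genes were the microtubule protein gene Dcx (2.82-fold), neurofilament Nefl (2.42-fold), the GDNF receptor Ret (2.38-fold) and Snap25 (2.03-fold). The second probe sets of Ret and Snap25 were each below the limit on 1 array, with bounds of -0.025 and 0.25 on the log2 scale. With the median of each gene's probe sets 2 of 23 genes were lower, and with loess 7 of 24. None of 11 glia and Schwann cell genes and 0 of 5 genes of interstitial cells of Cajal, the gut pacemaker cells, were 2-fold apart (medians 0.067 and 0.15, at the 44.7th and 63.2nd percentiles). Erbb3 was 1.65-fold and Pmp22 1.42-fold lower, Cnp 1.14-fold higher, and Kitl, the ligand of the Kit receptor, 1.44-fold higher. Both of these medians changed sign in some alternatives; the glial one was -0.14 with loess.

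Epithelial genes were measured in a squamous list and a simple and ciliated list, and the difference between these lists was not tested. Of 29 squamous epithelium genes, 6 were at least 2-fold lower and 0 higher (median -0.12, 13.2nd percentile). Among them were the cornified envelope genes Sprr1a (4.34-fold) and Sprr3 (2.81-fold), Krt19 (3.08-fold) and the transglutaminase Tgm1 (2.67-fold). Of 10 simple and ciliated epithelium genes, 4 were lower and 0 higher (median -0.58, 0.090th percentile). The keratins Krt7 and Krt8 were 5.96-fold and 2.37-fold lower, and the claudin Cldn4 3.90-fold. With the limit at the 25th percentile this median was -0.26, at the 5.38th percentile, with 5 genes lower and 3 higher. Of 30 fibroblast and matrix genes, 3 were lower and 0 higher (median -0.089, 21.5th percentile): Mfap4 (4.09-fold), Vim (2.56-fold) and Postn (2.31-fold). Of 7 tendon genes 1 was lower and 0 higher (median -0.034, 27.8th percentile), a median that changed sign in 2 of 8 alternatives.

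Vascular and blood cell lists showed no common direction. Of 17 endothelial genes, 2 were higher and 2 lower (median 0.24, 51.9th percentile), with Sox17 at least 2.52-fold lower and Emcn at least 2.19-fold higher. Of 6 erythroid genes, 1 was higher and 1 lower (median 0.20, 57.0th percentile), and of 22 white blood cell genes 2 were higher and 2 lower (median 0.096, 19.6th percentile). The leukocyte surface gene Ptprc was 8.57-fold higher at 1 probe set, with its second below the limit on both arrays. Lyz1 and C1qb were 2.24-fold and 2.06-fold lower at their brightest probe sets, and their other measured probe sets had log2 ratios of -0.032 and -0.19. With the median of each gene's probe sets, 0 of the 22 white blood cell genes were 2-fold lower. All 3 medians changed sign in some alternatives, and with loess the endothelial one was -0.046 and the white blood cell one -0.15.

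Lists for neighbouring organs, which dissection could bring, were mostly dim. Only 7 of 18 cartilage genes, 8 of 12 lung epithelium genes, 3 of 14 stomach genes and 8 of 18 thyroid and thymus genes were measured, with medians of 0.53, 0.66, 0.98 and 0.35 at the 97.7th, 97.9th, 99.48th and 91.9th percentiles. The ratio was only a bound for 3 of the 7 cartilage, 4 of the 8 lung, 0 of the 3 stomach and 7 of the 8 thyroid and thymus genes. Scgb3a2, a secretoglobin of airway epithelium, was 7.66-fold lower, Sox9 2.09-fold higher and the gastric peptide gene Tff1 1.97-fold higher. Rag1, the recombinase of developing lymphocytes, was at least 5.77-fold higher. Cd8a was 2.20-fold lower at its brightest probe set while 3 others went the other way. In the cardiac list, 3 of 8 genes were higher and 1 lower (median 0.75, 99.4th percentile), but Tnnt2, the cardiac troponin T that fetal skeletal muscle also makes, was 10.5-fold lower. The ratio was a bound for 5 of these 8. The 3 higher genes, Tbx5, Ryr2 and Nkx2-5, had wild-type signals of 113 to 630. Of 7 adipocyte genes 1 was lower, Lpl (3.41-fold), and 0 higher (median 0.41, 79.2nd percentile). The cardiac, adipocyte and lung medians turned negative with the limit at the 75th percentile (-1.62, -0.10 and -0.025).

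Among general cell processes, respiratory chain genes were slightly lower. Of 33 oxidative phosphorylation genes, 27 had a ratio below 0 and 1 was 2-fold lower (median -0.29, 0.33rd percentile), although its 3 brightest members went both ways: Uqcrb and Atp5a1 were 1.54-fold and 1.49-fold higher and Cox5b 1.13-fold lower. Another Atp5a1 probe set had a log2 ratio of -0.95. None of 29 cell cycle genes was 2-fold apart (median -0.13, 18.2nd percentile), and Mki67 was 1.10-fold lower. None of 16 ribosomal protein genes was 2-fold apart (median 0.23, 93.9th percentile). Of 18 immediate early genes 5 were lower and 0 higher (median -0.24, 2.49th percentile), with Egr1 4.05-fold, Fos 3.37-fold and Nr4a1 3.14-fold lower. With the limit at the 75th percentile 3 of 12 were lower (median -0.18, 21.9th percentile). Of 18 hypoxia and glycolysis genes, 3 were lower, Tpi1 (2.84-fold), Pkm (2.77-fold) and Aldoa (2.01-fold), and 1 higher, Adm (2.02-fold), with a median of -0.12 at the 34.6th percentile. Of 14 p53 target and apoptosis genes 3 were lower and 1 higher (median 0.055, 57.7th percentile), and Pmaip1 was 6.06-fold lower. Of 13 interferon response genes 1 was lower, Rsad2 (2.05-fold), and 0 higher (median 0.12, 37.8th percentile). Other probe sets of Rsad2 had bounds of 0.26 and -0.42 on the log2 scale, and with the median of each gene's probe sets 0 of the 13 were lower. None of 10 housekeeping genes was 2-fold apart (median 0.012, 48.6th percentile) at its brightest probe set. Actb's second probe set read 12780 and 84999, 6.65-fold higher, and a Pgk1 probe set was 2.57-fold lower; with the median of each gene's probe sets 1 of the 10 was 2-fold higher. The p53, interferon and housekeeping medians changed sign in some alternatives, with loess giving -0.17 and -0.14 for the first pair.

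Sex-linked genes differed between the arrays. Xist, the transcript of the inactive X chromosome, read 42465 on the wild-type and 24254 on the null-labelled array, 1.75-fold lower. The Y-linked genes Eif2s3y and Kdm5d were at least 4.91-fold and at least 2.37-fold higher, from wild-type signals of 10.6 and 160. These were the 3 measured genes of the list (median 1.24, 98.8th percentile), and its median was -0.014 with the limit at the 75th percentile. The sex of the embryos is not given in the labels.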

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

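All tests below were chosen after the result was seen, except those on scanner saturation and on X-linked genes that escape inactivation.

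The hybridization controls, bacterial and phage cRNAs added to each sample to check the hybridization, are outside the gene comparison and drew attention because their 18 probe sets read higher on the null-labelled array, by a median log2 ratio of 1.84 (range 1.57 to 2.11), or 3.57-fold, while the 27 poly-A control probe sets had a median of 0.78 (range -0.60 to 1.60). Probe sets below the low-signal limit on both arrays were also higher there, with a median raw log2 ratio of 0.46 over 18345 probe sets, and the measured genes had medians of 0.30, 0.038 and -0.066 in 3 equal groups from dim to bright. Loss of muscle transcripts alone, which would raise all other genes alike, stays open: the dimmest of 3 equal groups of the 10266 genes outside the muscle lists exceeded the brightest by 0.25 (95% bootstrap interval 0.22 to 0.28), but this repeats the pattern and unlisted muscle genes remain in it, and among 351 genes of the lists of other cell types and processes the difference was 0.16 (-0.042 to 0.33). A larger scaling factor on the null-labelled array, which would lift background with signal, stays open. The hybridization controls drew attention to it and so do not test it. The poly-A controls do not all read higher. In their 9 pairs, the 3' probe sets had log2 ratios of 0.45 to 1.60 and the 5' ones -0.60 to 0.78. The poly-A controls thus also carry a difference between the ends of the transcript and do not decide it. The labelling and amount of cRNA, the hybridization, the amount of control added and genotype also stay open and were not tested.

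The smooth muscle contractile list read higher on the null-labelled array, with a median of 0.45. The offset of dim probe sets is argued against by the random lists, which were matched on signal and had a median of 0.004 (SD 0.11). Loess on signal removes the same trend that the matching removes. Its result, a median of 0.51 above all random lists (percentile 100), is therefore no separate test. A lower share of striated muscle would raise every other cell type alike. The pooled median of 16 lists of other cell types and organs (201 genes) was 0.013. The smooth muscle median exceeded it by 0.44 (95% bootstrap interval over genes 0.16 to 0.66), and by 0.60 with loess (0.25 to 0.77). With 5 of these lists, the comparison made first, the difference was 0.55. The pooled lists did not move alike. Simple and ciliated epithelium had a median of -0.58. The cartilage, lung, stomach and cardiac lists, of 3 to 8 measured genes each, had higher medians (0.53, 0.66, 0.98 and 0.75) than smooth muscle. The pool is thus no single baseline, and the intervals cover genes of 2 arrays only. How much of the smooth muscle difference came from a lower striated share therefore stays open. Saturation of the scanner on the wild-type array, whose highest signal was 2.78-fold below that of the other array, could inflate the 3 brightest members, but the 28 others had a median of 0.40, at the 99.97th percentile of matched random lists. More smooth muscle RNA in the null-labelled tissue may be proposed as a hypothesis, and it cannot be separated from variation between embryos or dissections with 1 array per genotype.

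Y-linked genes read higher and Xist lower on the null-labelled array: 3 of 9 Y-linked probe sets were above the limit on the null-labelled array only, 0 on the wild-type array only, and all 3 Xist probe sets were lower. The offset of dim probe sets stays open. All 9 Y-linked probe sets were below the limit on the wild-type array. Of all 24954 such probe sets, 26.5% were above it on the null-labelled array. The mean bound of the 9 was 0.42 (log2), at the 98.03rd percentile of random sets of 9. It was at the 68.4th without the highest member, an Eif2s3y probe set. Bounds cap the ratios, and the raw log2 ratios of the 3 above the limit were 7.83 (Eif2s3y), 4.50 (Uty) and 2.85 (Kdm5d). The other Y-linked probe sets ranged from -0.47 to 1.52, and probe sets below the limit on both arrays had a median of 0.46. The 3 were picked by being above the limit, so these values do not settle it. More male tissue in the null-labelled sample would also lower X-linked genes that escape inactivation, and the 12 measured probe sets of Kdm6a, Kdm5c, Eif2s3x and Ddx3x had a median log2 ratio of -0.21 (95% bootstrap interval over probe sets -0.43 to 0.038), which includes 0 and leaves this open. Xist remained at 24254 there, so a mixture of sexes stays open too, and an effect of genotype on these genes was not tested.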

How the results depend on the processing

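No paired analysis was possible because each genotype has 1 array; for the same reason no array could be left out. The medians of the striated sarcomere, coupling, myogenic regulator, neuromuscular junction, energy metabolism, dystrophin complex and respiratory chain lists stayed negative, and those of both smooth muscle lists positive, in all 8 alternatives. A list median was counted as moved when it differed from the main value by more than 1 SD of the matched random lists. The causes of the shifts were not tested, except that a limit or its removal changes which genes are measured. Of the 125 named genes at least 2-fold apart, 121 reversed in none of the alternatives that gave them a value, which was 110 with the limit at the 75th percentile, 118 without _x_at and _s_at probe sets and all 125 in the others; those that reversed were Polr3k (0.026 with the median of probe sets, 0.47 without _x_at and _s_at probe sets), Hspb8 (-0.046 and -0.39), Cd8a (0.38 and 0.80) and, with the median of probe sets, Mdm2 (0.19). The 4-fold threshold gave 21 higher and 142 lower genes. The percentile of the cartilage list was 95.8 among random lists not matched on signal.

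Loess gave 449 higher genes, and medians of -1.08 for myogenic regulators, -2.65 for fast and -2.36 for shared sarcomere, -0.40 for dystrophin complex, -0.14 for glia, -0.79 for simple epithelium, 0.30 for cartilage, 0.30 for lung, 0.39 for cardiac, -0.046 for endothelium, -0.15 for white blood cells, -0.17 for p53 targets, -0.14 for interferon and 0.33 for Wnt. Quantile normalization gave -1.07 for myogenic regulators, -2.33 for fast sarcomere, 0.32 for cartilage, 0.33 for lung, 0.44 for cardiac, -0.040 for endothelium, -0.078 for white blood cells, -0.14 for p53 targets, 0.055 for ribosomal proteins, -0.10 for interferon, 0.53 for Hedgehog and 0.34 for Wnt.

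The limit at the 25th percentile gave 2742 higher and 1232 lower genes, and medians of -2.04 for fast, -4.34 for embryonic, -3.90 for slow and -3.11 for shared sarcomere, -1.05 for coupling, -1.12 for neuromuscular junction, -0.66 for dystrophin complex, -0.26 for simple epithelium, 0.84 for cartilage, 0.51 for stomach, 0.91 for thyroid and thymus, -0.43 for immediate early, 0.49 for Hedgehog and 1.77 for sex-linked genes. The limit at the 75th percentile gave 148 higher and 383 lower genes, a log2 ratio of -1.54 for Myf5, and medians of -2.46 for fast, -4.67 for embryonic and -2.77 for slow sarcomere, -0.84 for coupling, -0.57 for dystrophin complex, 0.19 for smooth muscle regulators, -0.025 for lung, 0.43 for stomach, -1.62 for cardiac, -0.10 for adipocyte, -0.22 for endothelium, -0.12 for erythroid, -0.31 for white blood cells, -0.12 for p53 targets, 0.37 for Wnt, -0.10 for TGF-beta and -0.014 for sex-linked genes, so that the lung, cardiac, adipocyte, endothelial, erythroid, white blood cell, p53, TGF-beta and sex-linked medians changed sign, as did those of glia (-0.12), interferon (-0.054) and housekeeping genes (-0.0095). With no limit there were 3548 higher and 1704 lower genes, the spread between probe sets rose to 1.09, and medians were -2.61 for fast, -4.31 for embryonic, -3.85 for slow and -3.34 for shared sarcomere, -1.02 for coupling, -0.66 for dystrophin complex, -0.27 for simple epithelium, 0.85 for cartilage, 1.19 for thyroid and thymus, -0.42 for immediate early, 0.39 for interferon, 0.58 for Hedgehog and 1.72 for sex-linked genes.

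The median of probe sets gave -0.63 for myogenic regulators, -1.03 for coupling, -0.71 for energy metabolism, 0.22 for smooth muscle regulators, 0.36 for Wnt and 0.72 for sex-linked genes. Without _x_at and _s_at probe sets the medians were -3.71 for fast and -3.60 for slow sarcomere, 0.54 for thyroid and thymus and -0.28 for hypoxia. Signal near the limit bounds the rest: the genes below it on 1 array have no measured ratio.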

Other observations

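In the Wnt list, 7 of 20 measured genes were at least 2-fold higher on the null-labelled array and 1 was lower, and the median log2 ratio of 0.55 lay above all 10000 random lists. It was 0.33 with loess. The higher genes were 5 with loess or quantile normalization, 4 with the median of each gene's probe sets and 3 of 12 with the limit at the 75th percentile. The secreted Wnt modulator Sfrp2 was 2.88-fold higher and the transcription factor Lef1 at least 2.56-fold, while the Wnt inhibitor Wif1 was at least 4.03-fold lower. The R-spondin Rspo2 was 2.72-fold higher at its brighter probe set. Its other probe set, below the limit on the null-labelled array, had a bound of -0.17 on the log2 scale. In the Hedgehog list, 3 of 10 were higher and 0 lower (median 0.30, 96.8th percentile, and 85.8th among random lists not matched on signal). With the median of each gene's probe sets 1 was higher (median 0.38). The ligand Shh was 2.19-fold higher, its receptor Ptch1 2.41-fold and Hhip 4.25-fold. Second probe sets of Shh and Ptch1, below the limit on the wild-type array, had bounds of 0.60 and 0.38 on the log2 scale. Other measured probe sets of Hhip had a log2 ratio of 1.04 and a bound of 1.12. Hhip is counted in the list of smooth muscle regulators too. Ptch1 and Hhip are known transcriptional targets of the pathway. Of 21 TGF-beta and BMP genes 4 were lower and 1 higher (median 0.059, 53.3rd percentile, negative in 3 of 8 alternatives), with Tgfb2 3.14-fold, the activin antagonist Fst 2.73-fold and Ccn2 2.16-fold lower and Inhba 2.52-fold higher. Of 23 IGF, FGF and HGF genes 3 were lower and 1 higher (median -0.088, 13.2nd percentile). The growth factor Hgf was 2.80-fold higher and its receptor Met 2.32-fold lower, and Igfbp2 was 3.04-fold lower. Fgfr4, which myoblasts express, was 4.32-fold lower at its brightest probe set, and another had a bound of 0.34 on the log2 scale.

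Outside the lists, the largest lower ratios were those of Atp1b4 (at least 36.8-fold), Tceal7 (at least 29.6-fold), the caveolar gene Cavin4 (at least 24.8-fold) and Lrrn1 (20.5-fold). Synpo2l was 18.4-fold lower at its brightest probe set, with another at a bound of 0.51 on the log2 scale. The imprinted noncoding RNA Rian was 14.8-fold lower, and its 4 probe sets ranged from -3.88 to -1.05. Psca was 12.2-fold lower. Atp1b4, Tceal7, Cavin4 and Psca had 1 probe set each. Samhd1 was 11.6-fold lower, and its 4 measured probe sets ranged from -3.96 to -0.34. Polr3k (19.2-fold) and Psmd6 (15.0-fold) rested on 1 probe set each, and others of the same genes read up to 0.47 and 0.22. Among the largest higher ratios, Hspb8 (6.32-fold), Fbxw2 (5.32-fold), Srr (4.62-fold) and Cmtm7 (4.58-fold) had a probe set in the opposite direction. Uroc1 was 5.62-fold higher, and its other probe set had a bound of 0.44 on the log2 scale. Lrrc10b (4.70-fold) and Serpinb6e (4.57-fold) had 1 probe set each. Trbv1 (at least 4.88-fold), Miip (at least 4.67-fold) and Cldn34c1 (at least 4.52-fold) were below the limit on the wild-type array.

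Among the 4489 measured probe sets with no gene name or with several, 506 were at least 2-fold higher and 79 at least 2-fold lower on the null-labelled array. Dim probe sets read higher on that array, and how bright these probe sets are was not examined. The counts are therefore no measure of gained transcripts.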
